A study of Mus musculus with 4 samples.

How the data were processed

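RNA was measured in mesothelial cells of 4 C57BL/6 mice aged 10 weeks, with 1 library per animal and 1 group. Mesothelial cells form the single layer that lines the peritoneal cavity. Per the labels' protocols, each cavity was rinsed with 10 ml of saline and then digested at 37 °C for 20 min with trypsin and EDTA (0.25%, 5 ml). The detached cells were sorted as negative for CD45 and positive for both podoplanin and Gpm6a. Total RNA was depleted of ribosomal RNA before library preparation. The labels give no sex, no time of collection and no batch. Animals are numbered as in the sample titles, and the study describes them as separate animals.

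The deposited values are estimated counts per gene, 1 column per animal, in a table of 48425 genes by symbol. The submitters' processing notes name kallisto 0.43.1, edgeR 3.24.3, limma 3.38.3 and the mouse build GRCm38.p5, with no role for each, and the step from transcripts to genes is not given in the sources used here. Whether the library kit kept strand is not given either. The unit was read from the values. Between 99.75% and 99.95% of the nonzero values per library were not whole, taken as more than 0.000001 from a whole number. Among genes with 1 annotated transcript, 66.6% to 70.4% of the values between 0.5 and 2.5 lay within 0.1 of a whole number, against 20% by chance, so 1 unit is close to 1 read. Genes at 0 in every library were kept by the authors: 25489 genes were listed at 0 in all 4 columns and 22936 had a value.

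The library totals were 4569578, 4371817, 4554370 and 4090224 estimated counts for animals 1 to 4. A gene at 0 can lie as high as 3 counts allow, which is 0.683, 0.681, 0.619 and 0.756 CPM (counts-per-million over the effective library sizes described below) in animals 1 to 4 and 0.170 CPM over the group. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Estimated counts keep the length of the transcript, so a long gene collects more reads than a short one at the same number of molecules. Estimated counts also depend on how reads were split between near-identical transcripts.

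Estimated counts were rounded to whole numbers and scaled with TMM in edgeR 4.0.16 under R 4.3.3. CPM below are rounded counts over effective library sizes. Levels are given as mean ± SD over 4 animals, and log2 values are log2(CPM + 0.5). Each pair of libraries was compared over the genes that reached a minimum count in the pair, which were 11848 to 12246 genes. The chi-square per gene ranged from 11.5 to 28.9, far above the sampling noise, so all 4 libraries were kept as separate replicates. Pearson's r of log2 values across genes, which are not independent replicates, was 0.902 to 0.929. It was taken over genes with a minimum count over the 4 libraries together.

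No contrast between groups exists in this series, so the test across genes was of the level itself. For each gene a quasi-likelihood F test of edgeR asked whether the level lay above 1 CPM, one-sided, with Benjamini-Hochberg adjustment over 48425 genes and a threshold of 0.05. The packaged test function does not take a design with an intercept only. The same statistic was computed from the fitted and null deviances and checked against the packaged function on a simulated design that it accepts. In counts simulated with the common spread of these data (biological coefficient of variation 41.9%), 1.5% of 200 genes at a true level of 1 CPM, 59% of 200 at 2 CPM and 99.5% of 200 at 4 CPM were called. Every gene was simulated with that same spread. These shares therefore do not give the false-call rate for genes that vary more between animals.

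A set of 38 gene lists and 20 gene pairs was fixed before the data were examined, as were the tests and most alternatives. Each cell-type list was summarised per animal by the median log2 value of its members. The mesothelial list was set against 13 other cell-type lists within each animal by an exact two-sided sign-flip permutation test, whose smallest p with 4 animals is 0.125. Podoplanin and Gpm6a were left out of the mesothelial list there, and genes held by both lists were left out of both. Gene pairs were compared by limma 3.58.1 on the within-animal log2 difference, two-sided, with Benjamini-Hochberg adjustment over 20 pairs. In pairs simulated with an SD of 0.68 log2, 9 of 10 with a log2 difference of 1 and 0 of 10 with none were called. List medians were ranked against 10000 random lists of the same size. To find lists that vary together between animals, the SD over animals of the list's mean deviation was set against 10000 random lists matched on mean expression in 20 bins, for lists with at least 5 genes at 1 CPM. In simulation over 13737 genes, 20 of 20 lists of 15 genes with a log2 difference of 1 between animals and 0 of 20 without one were called. The simulated noise was independent between genes. Most lists called in these data varied less than the simulated ones, and some held fewer genes. The simulation therefore gives neither the power nor the false-call rate for lists of related genes.

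The text names genes by a rule fixed before the data were examined. It takes the sort antigens, the 10 genes highest by mean, the 3 highest and the lowest member of each list, both genes of each pair, the 10 genes with the largest SD of log2 among those at 10 CPM or more, and every member of the sex-linked and serosal transcription factor lists. A few genes that the rule takes are not reported here. Other genes named in the text were chosen after their values were seen. Where several members of a list tied at 0, the rule took the one that comes first in the alphabet.

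Gene positions and transcript lengths came from GENCODE M21 on GRCm38. Symbols matched directly for 47597 genes and by an older name for 364, and 464 had no match. A gene's length was the median over its annotated transcripts. The genes highest by mean and by spread were aligned to all annotated transcripts with blastn 2.17.0, and another gene that matched at 95% identity or more over at least 200 bases was counted as sharing sequence.

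Alternatives were library size alone in place of TMM, leaving out each animal, pseudocounts of 0.1 and 1, other thresholds and filters, limma with voom weights, means in place of medians, division by transcript length, other sets for the random lists and other moderation of the pair test. Size factors of DESeq2 1.42.0 were added after the data were seen, as were length division for the cell-type lists, random lists from genes with a count, and the spread over genes with a count. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.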

Results

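The transcriptome of sorted mouse peritoneal mesothelial cells was profiled in 4 animals, with 4090224 to 4569578 estimated counts per library. The series holds 1 group and no treatment, and its stated purpose is the gene expression of mesothelium at homeostasis. The comparisons it allows are of levels against a fixed threshold, of genes and gene lists within an animal, and of animals with each other. Levels are CPM as mean ± SD (n = 4). They are not divided by transcript length unless stated, so comparisons between genes depend in part on length.

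The RNA of the antigens used for the sort was measured first. Gpm6a, a neuronal-type membrane glycoprotein on chromosome 8 at 54954843 to 55060871, stood at 2220.5 ± 518 CPM. Pdpn, which encodes podoplanin and lies on chromosome 4 at 143267431 to 143299564, stood at 1094 ± 185 CPM. Ptprc, which encodes CD45, the leukocyte antigen that the gate excluded, had 3.19, 0, 0.206 and 0 CPM in animals 1 to 4, which is 15 counts in all. By edgeR's quasi-likelihood test Gpm6a and Pdpn lay above 1 CPM and Ptprc did not (adjusted p = 1). Since the cells were chosen on these antigens, their levels describe the gate.

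Of the 20 mesothelial genes, 19 lay above 1 CPM, and each of the 19 had a mean above 100 CPM. Upk3b, a uroplakin of mesothelium and urothelium on chromosome 5 at 136038496 to 136046487, reached 4145 ± 400 CPM. The keratin Krt19 reached 2274 ± 871 CPM. Msln, the gene of mesothelin on chromosome 17 at 25748613 to 25754378, reached 2272 ± 477 CPM. The uroplakin Upk1b stood at 2234 ± 334 CPM, the keratin Krt7 at 814 ± 62.9 CPM and the tight junction gene Cldn15 at 756 ± 129 CPM. Calb2, the gene of calretinin on chromosome 8 at 110137502 to 110168210, was the exception, with 0 counts in every animal, below the 0.170 CPM that 3 counts over the group allow.

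The median of the mesothelial list, without Pdpn and Gpm6a, was 9.14 on the log2 scale. It was higher than the medians of all 13 other cell-type lists in 4 of 4 animals (exact sign-flip permutation p = 0.13 for each list, the smallest that 4 animals can give). The nearest was the fibroblast list, with a gap of 2.41 ± 0.58 on the log2 scale, and the next was the smooth muscle and pericyte list, with a gap of 6.35 ± 0.10. The other lists had medians near 0 counts. Their gaps of 9.47 to 10.14 are set by the pseudocount and are not folds.

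**Figure D1:**
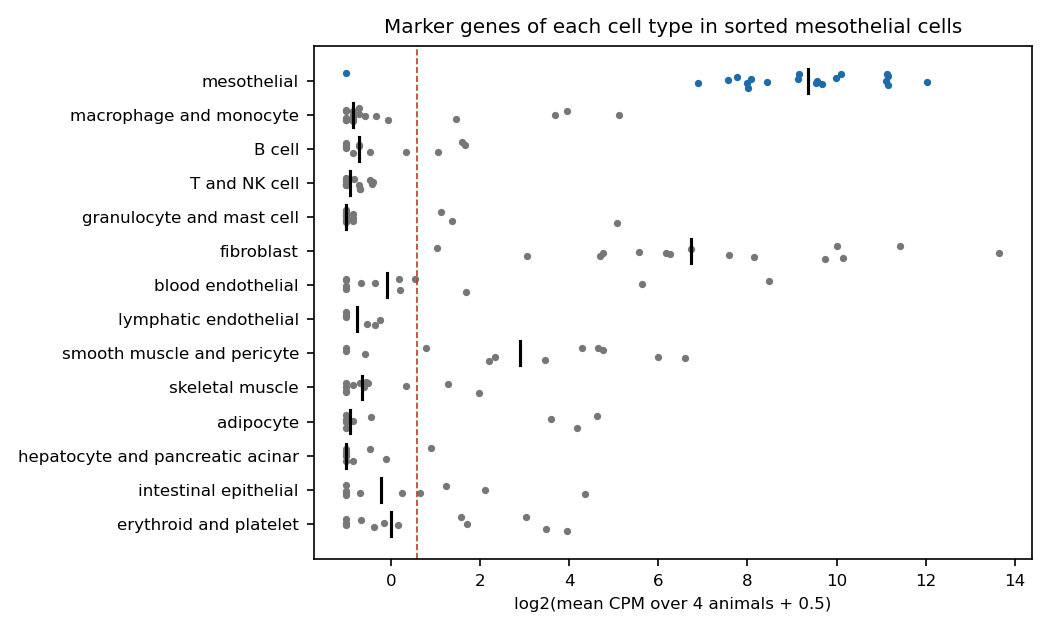
Mean expression over 4 animals of each marker gene, as log2(CPM + 0.5) on the horizontal axis, in 14 cell-type lists. Each point is a gene, the black bar is the median of the list, the mesothelial list is in blue and the dashed line marks 1 CPM; 19 of the 20 mesothelial genes and all 15 fibroblast genes lie to the right of the line, while most members of the leukocyte, endothelial, skeletal muscle, liver and gut lists lie to its left.

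Fibroblast matrix genes were abundant. Of the 15 fibroblast genes 14 lay above 1 CPM. Dcn, the small matrix proteoglycan decorin, on chromosome 10 at 97479609 to 97518143, stood at 12851 ± 1800 CPM, Col3a1 at 2725 ± 859 CPM and Col1a2 at 1132 ± 314 CPM. Other members of the list were lower. Col1a1, Col6a1, Col14a1 and Col6a2 had means of 1029, 848, 282 and 193 CPM. Mfap5 had 105 ± 60.4 CPM, Lum 76.4 ± 42.7 CPM, Fbn1 71.3 ± 7.34 CPM, Col6a3 47.3 ± 21.8 CPM and Thy1 26.6 ± 11.1 CPM. Pdgfra, the PDGF receptor alpha, had 25.4 ± 7.44 CPM, Dpt 7.86 ± 6.29 CPM and Pi16 1.55 ± 0.722 CPM, and Pi16 did not pass. In the smooth muscle and pericyte list 8 of 12 passed, led by Acta2 at 96.3 ± 44.7 CPM, Smtn at 63.4 ± 5.31 CPM and the potassium channel gene Kcnj8 at 26.6 ± 13.6 CPM, while Lmod1 had no count.

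Leukocyte genes were sparse. In the macrophage and monocyte list 3 of 20 passed, namely Csf1r (the receptor for colony-stimulating factor 1) at 34.5 ± 4.97 CPM, the phagocytic receptor Mertk at 14.99 ± 5.07 CPM and Cd68 at 12.3 ± 4.65 CPM, and Aif1 had no count. None of the 12 B cell genes and none of the 14 T and NK cell genes passed in the edgeR test. At unadjusted p under 0.05 by edgeR these were 2 and 0 genes, and with voom weights in limma 0 and 0. The highest B cell genes were Igkc at 9.79, 0.908, 0 and 0 CPM, Ighm at 10.0, 0, 0 and 0 CPM, and Cd79a at 5.92, 0.454, 0 and 0 CPM in animals 1 to 4, and Blk had no count. The highest T and NK cell genes were Lck at 0.258 ± 0.516 CPM, Cd2 at 0.241 ± 0.357 CPM and Cd3d at 0.222 ± 0.186 CPM, and Cd4 had no count. Among 14 granulocyte and mast cell genes only Hdc, the histamine-forming enzyme, passed, at 33.0 ± 9.10 CPM. Ms4a2 had 2.10 ± 1.91 CPM, Cxcr2 1.68 ± 0.576 CPM and the mast cell protease gene Cma1 no count.

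Other cell types of the body wall and viscera gave few transcripts. In the blood endothelial list 3 of 12 passed, namely Esam at 359 ± 25.4 CPM, the VEGF receptor Kdr at 49.4 ± 14.7 CPM and Tek at 2.74 ± 3.58 CPM, while the endothelial cadherin Cdh5 had no count. None of 6 lymphatic endothelial genes passed in the edgeR test (0 at unadjusted p under 0.05, 0 by limma with voom weights): Mmrn1, Reln and Prox1 lay at 0.341, 0.285 and 0.189 CPM on average and Ccl21a had no count. In the skeletal muscle list 1 of 12 passed, Actn3 at 3.45 ± 2.36 CPM. Mylpf had 1.92 ± 0.617 CPM, Acta1 0.775 ± 0.512 CPM and Ckm no count. Of 10 adipocyte genes 3 passed, Lipe at 24.3 ± 5.07 CPM, Lpl at 17.5 ± 10.2 CPM and Fabp4 at 11.6 ± 1.82 CPM, and Adipoq had no count. None of 10 hepatocyte and pancreatic acinar genes passed in the edgeR test (0 at unadjusted p under 0.05, 0 by limma with voom weights), with Apoa1 at 1.37 ± 2.42 CPM, Cpa1 at 0.422 ± 0.432 CPM, Apoa2 at 0.228 ± 0.322 CPM and Alb at 0. Of 10 intestinal genes 2 passed, Lgals4 at 20.0 ± 6.36 CPM and Lgr5 at 3.82 ± 4.72 CPM. Krt20 had 1.87 ± 3.60 CPM and Alpi no count. Of 12 erythroid and platelet genes 3 passed, Itga2b at 15.1 ± 4.76 CPM and the globins Hbb-bs at 10.7 ± 10.8 CPM and Hba-a2 at 7.63 ± 8.69 CPM, and Gp1bb had no count. A pass concerns the mean over animals, and several of these genes lay under 1 CPM in some animals. In animals 1 to 4 Hbb-bs had 3.87, 23.6, 15.3 and 0 CPM and Hba-a2 0.228, 17.0, 13.0 and 0.252 CPM. Lgr5 had 0, 0.681, 10.3 and 4.28 CPM and Tek 1.59, 0.681, 0.619 and 8.06 CPM. Reads of the globin paralogs can be shared between them.

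Over all genes of the table, 11957 genes lay above 1 CPM by edgeR's quasi-likelihood test. The mean was at least 1 CPM for 13737 genes, at least 10 CPM for 8774, at least 100 CPM for 1741 and at least 1000 CPM for 129. The gene with the highest mean was C3, the central complement component, on chromosome 17 at 57203970 to 57228136, at 13775 ± 1610 CPM. It was followed by the long non-coding RNA Gm26809 at 13424 ± 3035 CPM, Dcn, Actb at 10652 ± 2202 CPM and the secreted antiprotease Slpi at 9906 ± 3666 CPM. The iron store gene Fth1 came next at 9028 ± 1576 CPM, then the ubiquitin gene Ubb at 8880.2 ± 131 CPM, the caveola gene Ptrf at 7008 ± 983 CPM, the class I MHC gene H2-D1 at 6594 ± 1627 CPM and the pseudogene Gm1821 at 6086 ± 297 CPM. Several of these levels are uncertain because their transcripts share sequence with other genes. Gm1821 matches Ubb at 98.5% identity over 685 bases, Gm26809 matches 4 other genes, H2-D1 matches 5 and Actb 2, and Fth1 matches 1.

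Transcription factors of the serosal lining were led by Osr1 at 214 ± 86.3 CPM, Wt1 at 188 ± 31.9 CPM and Bnc1 at 118 ± 29.3 CPM. Wt1, the Wilms tumour gene, lies on chromosome 2 at 105126529 to 105173616. Of the 18 factors in this list 10 lay above 1 CPM, the others of these being Gata6 at 114 ± 25.3 CPM, Nr2f2 at 95.02 ± 27.9 CPM, Hand2 at 30.5 ± 3.10 CPM, Isl1 at 22.9 ± 13.9 CPM, Tbx18 at 8.78 ± 3.22 CPM, Sox9 at 4.06 ± 3.98 CPM and Foxf1 at 2.60 ± 1.44 CPM. Tcf21, Nr2f1, Hand1, Tbx5 and Gata4 had means of 2.05, 2.04, 1.88, 1.63 and 1.20 CPM and did not pass. Lhx2 had 4 counts and Nkx2-5 none. In the retinoic acid pathway 12 of 18 genes passed. The retinaldehyde reductase Dhrs3 stood at 741 ± 400 CPM, the retinoic acid-forming enzyme Aldh1a2 at 252 ± 29.1 CPM and Aldh1a1 at 222 ± 169 CPM, and the binding protein gene Crabp1 had no count.

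Complement genes were abundant, with 11 of 18 above 1 CPM. Besides C3, Serping1 (the C1 inhibitor) reached 5057 ± 379 CPM and Clu 3618 ± 732 CPM, while C6 of the terminal pathway had no count. In the list of myeloid growth factors and chemokines 13 of 20 passed. The B cell chemokine Cxcl13 had 835 ± 300 CPM, the alarmin Il33 489 ± 266 CPM and the neutrophil chemokine Cxcl1 444 ± 429 CPM, and Il1b had no count. All 9 class I presentation genes passed, led by H2-D1, B2m at 3724 ± 1325 CPM and H2-K1 at 2736 ± 227 CPM, with the activator Nlrc5 lowest at 13.7 ± 4.18 CPM. Class II presentation genes were present as well. Of 9 such genes 7 passed, among them the invariant chain gene Cd74 at 1438 ± 382 CPM, H2-Ab1 at 185 ± 49.3 CPM and H2-Aa at 166 ± 44.1 CPM, beside Ptprc at 0.848 ± 1.56 CPM. The leukocyte cathepsin gene Ctss of the same list had 3 counts in all. Of 15 interferon response genes 14 passed, led by Ifit3 at 271 ± 135 CPM and Irf1 at 206 ± 66.7 CPM, with Mx1 at 0.527 ± 0.780 CPM. Of 16 pattern recognition genes 10 passed, led by Nod1 at 109 ± 34.4 CPM, Myd88 at 76.3 ± 7.83 CPM and Ifih1 at 61.3 ± 22.4 CPM, and Tlr7 had no count.

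Genes of the serosal surface, matrix and junctions were counted by list. In the hyaluronan and lubrication list 11 of 15 passed. The syndecan Sdc4 had 4447 ± 641 CPM, Anxa1 3274 ± 456 CPM and the mucin Muc16 216 ± 50.7 CPM, and the hyaluronan synthase Has3 had 3 counts. In the coagulation and fibrinolysis list 13 of 15 passed, led by Anxa2 at 1937 ± 630 CPM and S100a10 at 457 ± 48.8 CPM, whose products form a plasminogen-binding complex, and by thrombomodulin (Thbd) at 280 ± 36.1 CPM. Tfpi2 had no count. Of 16 basement membrane genes 15 passed, led by Nid2 at 277 ± 72.4 CPM, Col18a1 at 166 ± 37.0 CPM and Lamb1 at 115 ± 23.7 CPM, whereas Lama1 had no count. Of 21 epithelial junction genes 14 passed, with F11r at 963 ± 15.97 CPM, Cldn15 and the connexin Gja1 at 400.7 ± 47.9 CPM highest, and Cldn4 at 0. Of 20 genes of epithelial to mesenchymal transition and TGF-beta signalling 16 passed, led by Vim at 1264 ± 130 CPM, Fn1 at 230 ± 145 CPM and Bmp4 at 208 ± 116 CPM, and Grem1 had no count.

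Immediate early and stress genes were abundant. All 22 passed, led by Fos at 4569 ± 829 CPM, the chaperone Hspa8 at 2650 ± 667 CPM and Klf6 at 1734 ± 681 CPM, with Egr2 lowest at 13.9 ± 15.1 CPM. The cells had been kept in trypsin at 37 °C for 20 min before sorting, and no undigested tissue is among the samples. Proliferation genes were low, with 9 of 16 above 1 CPM. Pcna had 63.8 ± 14.5 CPM, Top2a 9.29 ± 4.59 CPM and Mcm2 8.82 ± 3.94 CPM, and the mitotic kinase Bub1 had 5 counts.

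In the prostaglandin list 10 of 14 passed, led by Ptges3 at 799 ± 34.8 CPM, the prostacyclin synthase Ptgis at 590 ± 89.7 CPM and Ptgs1 (cyclooxygenase 1) at 277 ± 102 CPM, and Hpgds had 3 counts. In the insulin-like growth factor axis 9 of 11 passed, led by the binding protein Igfbp6 at 3070 ± 285 CPM, Igf1 at 482 ± 363 CPM and Igfbp5 at 392.5 ± 311 CPM, with Pappa at 0.714 ± 0.566 CPM. In the water and ion transport list 12 of 15 passed, led by Slc9a3r1 at 513 ± 193 CPM, Atp1b1 at 195 ± 61.5 CPM and the water channel Aqp1 at 125 ± 38.5 CPM, and the sodium channel subunit Scnn1b had no count. In the Wnt and R-spondin list 12 of 18 passed, with Wls at 378 ± 69.7 CPM, Sfrp2 at 288 ± 113 CPM and Rspo1 at 270 ± 11.8 CPM highest and Rspo2 at 0. All 13 mitochondrially encoded genes passed, from mt-Co3 at 3823 ± 845 CPM, mt-Co1 at 2747 ± 507 CPM and mt-Atp6 at 2453 ± 603 CPM to mt-Nd4l at 47.2 ± 17.2 CPM. All 12 housekeeping genes passed, with Actb and Eef1a1 at 4688 ± 676 CPM among the highest and Tbp lowest at 36.3 ± 8.08 CPM. Of 6 nuclear long non-coding RNAs 5 passed, with Malat1 at 1853 ± 140 CPM and Meg3 at 102 ± 27.3 CPM above Xist, and H19 at 1.93 ± 2.58 CPM lowest.

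These counts are from edgeR's test adjusted over all 48425 genes. Adjusted over the list alone, the number of genes above 1 CPM was 12 in the complement list, 5 in the erythroid and platelet list, 11 in the prostaglandin list and 5 in the sex-linked list, and it was the same as over all genes in the other lists. By limma with voom weights, adjusted over all genes, the counts were lower: 2 in the blood endothelial, 0 in the skeletal muscle, 1 in the intestinal, 2 in the erythroid and platelet and 2 in the sex-linked list. They were lower by 1 gene in the lists of the retinoic acid pathway, myeloid growth factors and chemokines, coagulation, epithelial to mesenchymal transition, proliferation and the insulin-like growth factor axis, and the same in all other lists. By the median of its members, a list ranked above 95% of random lists from the whole table in 26 of 38 cases. Against random lists of genes at 1 CPM or more it did so in 12 cases, among them the mesothelial, fibroblast, complement, basement membrane, stress, class I, class II, interferon and insulin-like growth factor lists.

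The pairs of alternative ligands, enzymes and structural genes showed which member prevailed, and 18 of 20 pairs differed by limma at an adjusted p under 0.05. Of the ligands of the colony-stimulating factor 1 receptor, Csf1 at 187 ± 18.8 CPM exceeded Il34 at 34.1 ± 7.42 CPM, by 2.45 on the log2 scale (SE 0.245, adjusted p = 0.000157 by limma, higher in 4 of 4 animals). After division by transcript length the difference was 0.83. Csf2 had 3 counts in all. The monocyte chemokine Ccl2 at 168 ± 126 CPM exceeded Cxcl12 at 6.18 ± 5.90 CPM. Hyaluronan synthase Has1 stood at 46.6 ± 13.8 CPM against 8 counts for Has2. Tgfb2 stood at 35.4 ± 7.56 CPM against 7 counts for Tgfb1. Tgfb3, which was in no pair and was not tested against Tgfb2, had a higher level at 143.9 ± 19.026 CPM. Gata6 exceeded Gata4, which had 23 counts, and Rspo1 exceeded Rspo3, which had 14. Aldh1a2 exceeded Aldh1a3, which had 14 counts, whereas Aldh1a2 and Aldh1a1 were not distinguishable (log2 difference 0.56, SE 0.538, adjusted p = 0.337 by limma), with Aldh1a2 higher in 2 of 4 animals.

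The plasminogen activator Plat at 134 ± 32.4 CPM exceeded the other activator, Plau, at 2.996 ± 0.846 CPM. C3 exceeded C4b at 1062 ± 484 CPM by 3.82 on the log2 scale. C4b has a close paralog with which reads can be shared. Ptgs1 exceeded Ptgs2 at 22.1 ± 7.99 CPM by 3.62 on the log2 scale, and by 5.35 after division by length. Msln exceeded Muc16 by 3.39, and by 5.87 after division by length. Igf1 exceeded Igf2 at 3.97 ± 3.74 CPM, and Col1a1 at 1029 ± 326 CPM exceeded Col4a1 at 43.2 ± 14.1 CPM. Among keratins, Krt19 exceeded Krt7 by 1.40 on the log2 scale (SE 0.334, adjusted p = 0.00875 by limma). Krt18 at 573 ± 63.1 CPM exceeded Krt8 at 347 ± 31.8 CPM by 0.72 (SE 0.240, adjusted p = 0.0292 by limma). That call was lost without animal 1, 2 or 4, at adjusted p = 0.18, 0.078 and 0.0974 by limma. Upk3b exceeded Upk1b by 0.90 (SE 0.219, adjusted p = 0.00888 by limma). It was lower by the same test after division by length (-0.69, adjusted p = 0.0188 by limma), and the call was lost without animal 1 or 2, at adjusted p = 0.0854 and 0.058. Cdh1 and Cdh2, the epithelial and neural cadherins, had 9 and 23 counts, and the pair did not pass (log2 difference -0.84, adjusted p = 0.155 by limma).

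The spread between animals was moderate for most genes. The median SD of log2 over the 4 animals was 0.42 for the 13737 genes at 1 CPM or more, with quartiles of 0.26 and 0.70, and 0.32 for the 8774 genes at 10 CPM or more. An SD above 1 was found for 1672 genes and above 2 for 95. The common biological coefficient of variation was 41.9%. The genes with the largest spread at 10 CPM or more were Gm9800, Xist, Bdnf, Gm17383, Ddx3y, Car3, Klf15, Gm26771, Pgk1-rs7 and Gm28438. Car3, a carbonic anhydrase, had 517, 5.45, 67.5 and 237 CPM in animals 1 to 4. Klf15, a transcription factor, had 37.8, 0.227, 4.95 and 32.3 CPM. Bdnf, a neurotrophin, had 59.0, 0.227, 19.8 and 89.5 CPM, and it shares 502 bases at 99.8% identity with another gene. The 5 genes Gm9800 (0, 70.6, 0 and 45.6 CPM), Gm17383 (0, 45.2, 44.0 and 4.79 CPM), Gm26771 (24.6, 6.81, 0 and 23.2 CPM), Pgk1-rs7 (0.910, 33.1, 22.3 and 0.504 CPM) and Gm28438 (24.4, 31.3, 0.206 and 12.1 CPM) share sequence with Ptma, Tuba1b, Sfrp2, Pgk1 and mt-Nd3, so their levels are uncertain.

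Genes of the sex chromosomes differed between animals. Xist, the RNA expressed from the inactive X chromosome, had 0.455, 119.8, 57.8 and 63.0 CPM in animals 1 to 4. Ddx3y of the Y chromosome had 79.9, 0.454, 1.45 and 1.01 CPM, Kdm5d 24.1, 1.59, 2.48 and 1.51 CPM, Eif2s3y 20.7, 0, 0.619 and 0 CPM, and Uty 9.33, 0.227, 0 and 0 CPM. Of these 5 genes 4 passed the edgeR test against 1 CPM, and Uty did not. The labels give no sex. Xist overlaps its antisense gene Tsix, and reads of the pair cannot be told apart without strand. The Y-chromosome genes do not rest on that pair. High Y-chromosome genes with little Xist read animal 1 as male, and the reverse reads animals 2 to 4 as female. Whatever else sets animal 1 apart cannot be separated from a difference in sex.

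Whole lists also shifted between animals. Of the 27 lists with at least 5 genes at 1 CPM, 10 varied more between animals than 95% of matched random lists. An adjusted share of random lists under 0.05 was found for 8. Lists of unrelated genes would give 1.4 by chance. Several of the lists hold related genes, such as globin paralogs or genes transcribed together, so 10 against 1.4 is not a measured excess. The widest was the erythroid and platelet list, which rests on 4 globin genes and Itga2b, with mean deviations of -1.42, 1.40, 1.38 and -1.36 on the log2 scale in animals 1 to 4. Some globin values in animals 1 and 4 lie near the floor, so the size of these deviations depends on the pseudocount. Their SD was 1.60 at a pseudocount of 0.5, 2.25 at 0.1 and 1.31 at 1. Interferon response genes deviated by 0.20, -0.45, 0.55 and -0.30. Myeloid growth factors and chemokines deviated by -0.26, 0.34, 0.38 and -0.46. Nuclear long non-coding RNAs, which include Xist, deviated by -1.11, 0.96, -0.16 and 0.30, and sex-linked genes by 1.81, -0.62, -0.40 and -0.79. Mitochondrially encoded genes, which are transcribed together, deviated by 0.25, -0.55, -0.05 and 0.34. The lists of class I presentation, the retinoic acid pathway, fibroblasts and class II presentation were the others. The adjusted shares were 0.020 and 0.031 for the first pair and 0.052 and 0.090 for the fibroblast and class II lists. Some of these calls rest on 1 animal. The percentile among random lists fell to 19.1 for the retinoic acid list without animal 3, to 83.2 for class I and 92.0 for mitochondrial genes without animal 2, to 67.8 for class II without animal 1 and to 85.8 for fibroblasts without animal 4. The sex-linked list was not tested without animal 1, since fewer than 5 of its genes are then at 1 CPM. The mesothelial list varied by an SD of 0.12 on the log2 scale, at the 75.04 percentile of its random lists. The percentile was 97.0 with library size alone and 95.25 with the median of members, and without animal 2 the SD was 0.014 at the 1.17 percentile.

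**Figure D2:**
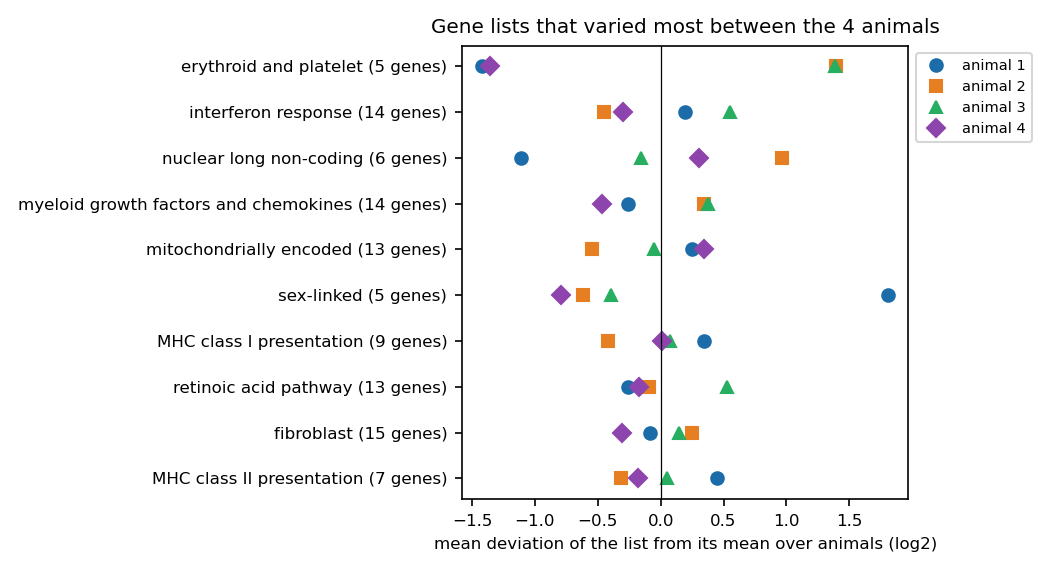
Mean deviation of each list from its mean over the 4 animals, in log2 units on the horizontal axis, for the 10 lists that varied more between animals than 95% of matched random lists. Each symbol is 1 animal; the erythroid and platelet list runs from -1.42 to 1.40 and the sex-linked list from -0.79 to 1.81, while class II presentation stays between -0.31 and 0.45.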

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

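Of 187 named levels and list deviations tested for a single animal far from the other 3, 15 were found, where chance alone gives 9.3, so several of them are within what chance produces. The only test on a source of these values concerns B cell transcripts in animal 1 and is given with the other observations, and the sources of the rest were not tested.

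Genes of several lists other than the sex-linked one gave part of these values, all on the log2(CPM + 0.5) scale. Ighm, the immunoglobulin mu chain, was 3.39 in animal 1 and -1.0 in the other 3, which had no count. Krt20, a gut keratin, was 2.96 in animal 2 against -0.46, -1.0 and -1.0 in animals 1, 3 and 4. Il34 was 5.51 in animal 3 and 4.93 to 4.96 in the others. Anxa1 was 11.34 in animal 3 and 11.77 to 11.78 in the others. Nid2 was 7.41 in animal 2 and 8.20 to 8.34 in the others. Smtn was 5.81 in animal 4 and 6.04 to 6.06 in the others. Hand1 was -1.0 in animal 3, which had no count, and 1.35 to 1.79 in the others.

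Sex-chromosome genes set animal 1 apart. Xist was -0.066 there and 5.86 to 6.91 in the others. Ddx3y was 6.33 in animal 1, Kdm5d 4.62 and Uty 3.30, while the highest values among the other 3 were 0.96, 1.57 and -0.46. These genes are not independent of each other, and the deviation of the sex-linked list (1.81 in animal 1) repeats them. Lists with 1 animal apart were the insulin-like growth factor axis (0.38 in animal 3), the mesothelial list (0.18 in animal 2) and the stress list (-0.14 in animal 3), with the other animals between -0.17 and 0.07.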

How the results depend on the processing

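The level count held within 1.5 times of 11957 genes under every alternative run. It was 11943 with library size alone, 11956 with DESeq2 size factors, 11663 with voom weights, 12256 after a filter on low genes, 12969 and 9230 at thresholds of 0.5 and 5 CPM, and 11692 to 11857 with an animal left out. All 13 cell-type lists stayed below the mesothelial list under each of 11 alternatives, and 53 of these gaps moved by more than 1 SD and 90 did not. The count of lists above random was 26 under the scalings, pseudocounts, means, length division and left-out animals. It fell to 12 against random lists of genes at 1 CPM or more and to 17 against genes with a count, which removes the genes at 0 from the random lists. The median SD between animals was 0.0 over all genes in the table, most of which are at 0 in every animal, and 0.32 to 0.44 in the other settings. List by list, 18 spreads rose above the 95% limit in some setting and 5 fell below it, and 3 named gene levels moved. The sex-linked list without animal 1 and at 5 CPM, and the erythroid and platelet list at 5 CPM, kept too few genes to test. The number of lists that vary together was 9 to 15, and the number of gene pairs that differ 16 to 19. Upk3b minus Upk1b turned from 0.90 to -0.69 on division by transcript length, so which of these uroplakins was higher depends on that correction. Cdh1 minus Cdh2 passed without animal 3 (-1.42, adjusted p = 0.00754 by limma), on few counts. Alternatives added after the data were seen were those with DESeq2 size factors, with genes that have a count and with length division of the cell-type lists. A pseudocount for the level count did not apply, since edgeR's test uses none, and no list member was missing from the table. No paired comparison between groups was possible because the series has 1 group, and the gene pairs and cell-type lists were compared within animals. Depth limits single genes near 1 CPM, where a library holds 4 to 5 counts.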

Other observations

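The lists used here were chosen after the data had been looked at. The tests on B cells, on Dcn, on fibroblast-restricted genes, on each clock arm alone and on library depth were chosen after their values had been seen. The clock and glucocorticoid lists were prompted by the spread of Klf15 and of other genes that were then left out of them.

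Several genes of the circadian clock differed between animals. Dbp, an output gene of the clock, had 61.9, 6.36, 23.9 and 64.8 CPM in animals 1 to 4, Ciart 12.1, 0.68, 2.48 and 18.4 CPM, Per3 90.4, 29.3, 47.1 and 99.8 CPM and Nr1d1 531, 193, 190.3 and 464 CPM. Arntl, a core activator that peaks opposite to these genes, had 5.46, 26.1, 25.8 and 5.04 CPM. Of the other genes taken for that arm, Clock had the same direction with smaller differences (24.1, 25.2, 28.9 and 20.7 CPM), while Npas2 (5.23, 2.72, 7.02 and 1.01 CPM) and Nfil3 (3.64, 5.45, 4.75 and 5.54 CPM) did not follow Arntl. Genes induced by glucocorticoids differed as well. Tsc22d3 had 3878, 573, 706 and 3005 CPM, Sgk1 1761, 277, 308 and 1364 CPM, Zbtb16 64.6, 11.6, 6.6 and 32.5 CPM and Fkbp5 53.5, 9.76, 12.2 and 13.1 CPM. Other targets moved less, with Cdkn1a at 52.6, 38.6, 48.9 and 59.7 CPM, and Errfi1 went the other way at 25.3, 32.5, 36.3 and 26.2 CPM. Other lists of the report also set animals 1 and 4 against animals 2 and 3, among them the globin-based erythroid and platelet list (-1.42, 1.40, 1.38 and -1.36 on the log2 scale), the mitochondrially encoded list (0.25, -0.55, -0.05 and 0.34), the myeloid growth factor and chemokine list (-0.26, 0.34, 0.38 and -0.46) and the fibroblast list (-0.09, 0.25, 0.15 and -0.31). Blood in the sample, RNA quality and a varying fibroblast share were not tested as sources of this split.

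The spread between animals may reflect the time of collection, which these values leave open. The 8 output genes deviated by 0.74, -1.21, -0.49 and 0.95 on the log2 scale in animals 1 to 4 and the 4 genes of the opposite arm by -0.21, 0.27, 0.57 and -0.64, a difference whose SD stood at the 100 percentile of matched random pairs of lists and at 99.9 or above with any animal left out, but the output genes carry it, since alone they stood at the 100 percentile, the opposite arm at 88.1 and the opposite arm without Arntl at 46.1. The 10 glucocorticoid targets deviated by 0.90, -0.54, -0.67 and 0.32. They stood at the 100 percentile of matched random lists, and with any animal left out too. The spread of Klf15 and of other genes had prompted this list and the clock lists. Klf15 was already higher in animals 1 and 4 (37.8 and 32.3 CPM) than in the others. The percentiles of these lists are therefore not separate evidence for a source, and leaving out an animal does not remove that choice. Since glucocorticoid release is itself rhythmic, stress at handling and clock phase stay open together. Thinning to the depth of the smallest library could not test library depth, because the totals, 4569578 at most and 4090224 at least, differ too little. The first component held 42.0% of variance before thinning and 42.4% after. With so few animals equal components would each hold a large share too, so these values do not make it a dominant axis. Its loadings before thinning were 0.62, -0.56, -0.42 and 0.36 in animals 1 to 4. By total counts, the deepest library (animal 1) and the shallowest (animal 4) lay on the same side. Animals 1 and 3, with close totals of 4569578 and 4554370, lay on opposite sides. The TMM factors were 0.961, 1.008, 1.064 and 0.97 in animals 1 to 4. They lay below 1 in animals 1 and 4 and above 1 in the others, which is the same split as in the loadings. Whether depth or its scaling is a source of that component therefore stays open. No biological explanation was tested against a group of the design, and the labels give no collection time.

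Class II genes in a gate that excludes CD45 may come from the mesothelial cells or from residual leukocytes. The median of 6 pan-leukocyte genes (Laptm5, Coro1a, Cd52, Cd53, Rac2 and Arhgdib) was at most 1.07% of the median of 6 class II genes in any animal, against the 10% set beforehand, although 1 of the 6, Arhgdib, stood at 546 ± 66.9 CPM and is not restricted to leukocytes here. In animals 2 to 4 the median of Cd79a, Cd79b, Ighm and Igkc was at most 0.23 CPM beside Cd74 at 1193 CPM or more, which argues against B cells there. In animal 1 that median was 7.85 CPM beside Cd74 at 2004 CPM, and whether B cells added to Cd74 in that animal cannot be told apart from other differences with 1 such animal. These tests concern cells of another type in the sample, and no biological explanation was tested, as the design has 1 group.

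Matrix genes could come from fibroblasts carried through the sort, a candidate source although the gate required Gpm6a as well as podoplanin. The SD over animals of the log2 ratio of Dcn to the fibroblast-restricted genes Dpt, Pi16, Lum, Mfap5 and Pdgfra was 0.52, which is 10.08 times its counting error, and this decides nothing because fibroblasts of different animals can differ in that ratio too. The restricted genes themselves varied together (share of random lists as variable 0.005), and this cannot be read as carry-over because they were picked after their values had been seen and the percentile fell to 89.4 without animal 2 and 94.4 without animal 4. Carry-over as the whole or a part of the source of the 12851 CPM of Dcn stays open. No biological explanation was tested.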
